A study of Homo sapiens with 18 samples.

How the data were processed

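The study measured RNA in U251-MG cells, an established human astrocytoma line, with 18 Affymetrix exon arrays. Cells received 500 µM arsenite, an oxidative stressor that stops translation and induces stress granules, or the vehicle DMSO, and RNA was harvested after 30 min. RNA was taken from whole lysate (input) or from RNA immunoprecipitates (RIPs) made with an antibody to TIAR or to G3BP1, which are RNA-binding proteins of stress granules. Some sample labels call the first antibody Tial, after TIAL1, the gene that encodes TIAR. The 6 groups (TIAR RIP, G3BP1 RIP and input, each stressed and unstressed) hold 3 biological replicates each, and no array was left out.

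The deposited values are log2 signals that the authors made with RMA (background correction, quantile normalization and median polish) in Affymetrix Expression Console, with 1 value per transcript cluster. The software version, the probe-set level and whether the 18 arrays were normalised together are not given in the sources used here. Values run from 1.64 to 14.53. Control probe sets are not marked in the table, so all transcript clusters were tested. The array medians differ between groups, so the values are not on fully equal scales. RIP and input values show the composition of each RNA sample and not how much RNA an antibody recovered. The number of arrays limits the precision, and signal near background cannot be separated from absence.

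Transcript clusters were named from the platform table. A single gene symbol was given for 14432 of them (65.6%), several symbols for 2408 (10.9%) and none for 5171 (23.5%). For gene-level statements the brightest transcript cluster of each of 14232 genes was used. A RefSeq table on GRCh38.p14, used for names only, changed 0 symbols.

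A linear model with 6 group means was fitted to all 18 arrays in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, without an intensity trend and without a filter. The residual degrees of freedom were 12 and the prior degrees of freedom 2.61. Moderated two-sided tests were adjusted by the Benjamini-Hochberg method over all transcript clusters within a comparison, and an adjusted p under 0.05 was called. There were 12 comparisons. Arsenite was compared with control in each RIP and in input, and each RIP with input and the RIPs with each other, in stressed and in unstressed cells. The differences of stress changes (each RIP against input, and TIAR against G3BP1) were tested as interaction contrasts. A stress-granule set holds the transcript clusters that were higher in a stressed RIP than in the same RIP without stress and higher in it than in stressed input. It does not ask for a stress change beyond that of input. Overlaps of comparisons with no shared arrays were set beside the number that independent lists would share. Where comparisons share arrays, the correlation of their changes was set beside the value from 20 simulations of unchanged groups. Errors of log2 changes are standard errors from the fit, and errors of group means are SD with n = 3.

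Of 31 gene lists, 28 had at least 5 members on the array and were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. The lists cover stress granule proteins, translation, ribosomes, oxidative phosphorylation, the proteasome, stress responses, the cell cycle, DNA replication and repair, glycolysis, long structural proteins, secretion, AU-rich mRNAs, splicing, ubiquitination, apoptosis, histones, zinc finger genes and markers of other cell types. Lists of small nucleolar RNAs (0 members on the array), mitochondrially encoded RNAs (2) and nuclear long noncoding RNAs (2) were too small. The results of 1 tested list are not given in the text or figures, though it counts among the 28.

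Genes named in the text follow a rule based on the largest called changes. Up to 10 are taken in each direction for the arsenite comparisons, 8 for stressed RIP against stressed input and 5 for the others. In comparisons of 2 groups, the arrays of these genes do not overlap between the groups. The interaction contrasts, the stress-granule sets, the shared changes and the list members were not checked for this. Up to 10 genes are taken per stress-granule set, for the genes in both sets and for the shared changes, up to 4 members with the smallest p per list, and always TIAL1, TIA1, G3BP1, G3BP2, ECT2 and AURKB. Chance alone separates 3 arrays from 3 in 10% of genes. XIST and Y-linked genes were left out. The design, the lists, the rule and the alternatives were set before the data were examined, apart from the setting without the 2 arrays that stand apart from their groups, which was added after seeing the data.

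The alternatives were a replicate block, a fit of the compared groups alone, an intensity trend with a robust prior, array weights, leaving out the lowest 25% or 50% of transcript clusters by mean, median centring, a further quantile normalization, cyclic loess, a floor at percentile 20 of each array, a minimum change of log2 1, 1 transcript cluster per gene, and leaving out each array. The pipeline was tested on simulated data in which 200 transcript clusters were changed. In the arsenite comparison of the TIAR RIP it recovered 36.8% of changes of log2 0.5, 75.8% of log2 1 and 100% of log2 2, with 6% false calls. For the interaction of G3BP1 RIP and input the corresponding shares were 11.8%, 54.5% and 93.9%. The simulated noise was drawn independently for each array, whereas 43.6% of the measured variance within groups lay on a shared axis. Fewer transcript clusters were changed than were called in these comparisons. The shares therefore need not hold for the measured data. Exon-level splicing was not analysed here, because the values are summarised per transcript cluster.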

Results

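RNA from U251-MG astrocytoma cells was measured on 18 exon arrays, with 3 arrays in each of 6 groups. The groups were input, TIAR RIP and G3BP1 RIP, from cells treated with 500 µM arsenite for 30 min or with DMSO. TIAR and G3BP1 mark stress granules, the cytoplasmic assemblies of stalled mRNA and protein that arsenite induces.

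The antibody separated the arrays more than arsenite did. Component 1 of a principal component analysis held 44.8% of the variance and set the TIAR RIPs apart from the G3BP1 RIPs. Component 2 held 27.9% and set both RIPs apart from input. The mean correlation of arrays was 0.987 between the stressed and unstressed TIAR RIPs, and 0.951 between the stressed TIAR and stressed G3BP1 RIPs. In stressed input, replicate 1 stood apart from its group, with a mean correlation of 0.98 and an upper quartile of 9.17. In the unstressed G3BP1 RIP, replicate 3 did so, with 0.98 and 9.45. Both arrays were kept, and results without both are given where they differ most.

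**Figure D1:**
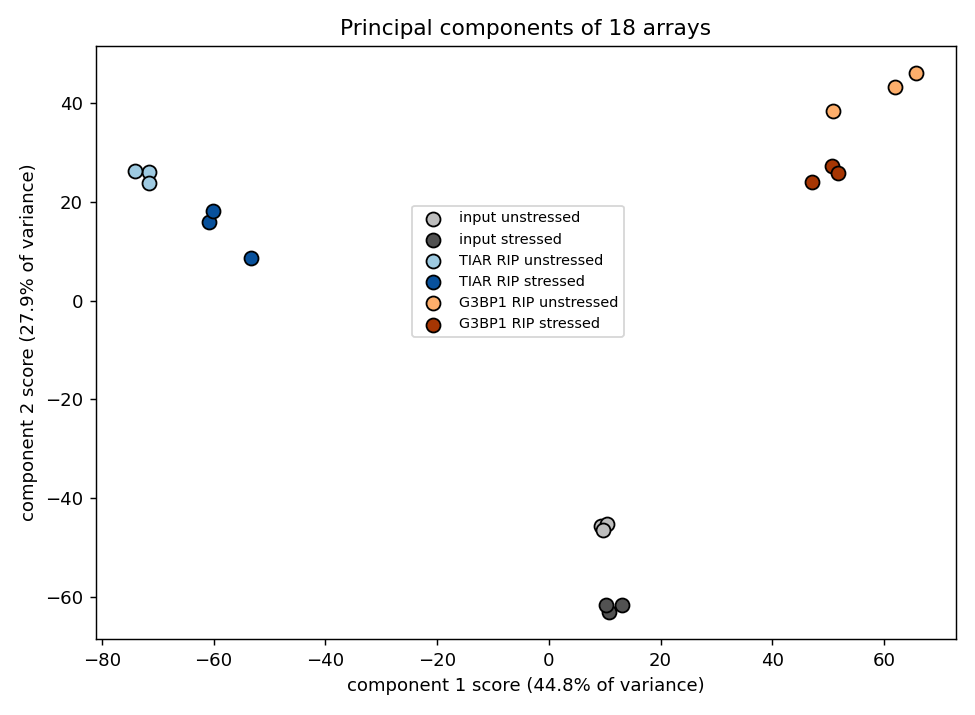
Scores of the 18 arrays on principal components 1 (44.8% of variance) and 2 (27.9%) of the log2 values, with 1 point per array and colour for the group. The TIAR RIPs lie at negative and the G3BP1 RIPs at positive scores of component 1, and the inputs at negative scores of component 2.

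ECT2, a gene of cytokinesis, and AURKB, a mitotic kinase, are named in the title of the series. ECT2 (transcript cluster 2652675) had stress changes of 0.58 ± 0.25 in the TIAR RIP (adjusted p = 0.173), -0.18 ± 0.25 in the G3BP1 RIP (adjusted p = 0.759) and -0.01 ± 0.25 in input (adjusted p = 0.99), with n = 3 arrays per group. AURKB (3744263) rose by 0.33 ± 0.08 in the TIAR RIP (adjusted p = 0.0153). Its values were 0.25 ± 0.08 in the G3BP1 RIP (adjusted p = 0.0609) and 0.25 ± 0.08 in input (adjusted p = 0.064), and the TIAR change beyond that of input was 0.09 ± 0.12 (adjusted p = 0.806). Against input, AURKB was lower in the TIAR RIP with stress (-0.86 ± 0.08) and without (-0.95 ± 0.08).

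Of the antibody targets and their relatives, G3BP1 mRNA (2835960) rose by 0.44 ± 0.13 in input (adjusted p = 0.0315). In the G3BP1 RIP its stress change was -0.33 ± 0.13 (adjusted p = 0.103), and the difference from the change of input was -0.77 ± 0.18 (adjusted p = 0.00791). The mRNA of TIAR, TIAL1 (3309629), had changes of -0.11 ± 0.15 in the TIAR RIP (adjusted p = 0.833) and -0.21 ± 0.15 in input (adjusted p = 0.427). TIA1 (2558511), which encodes a relative of TIAR, was higher in the stressed TIAR RIP than in input (1.20 ± 0.20), and so was G3BP2 (2773756; 0.78 ± 0.15), while TIAL1 was lower (-0.73 ± 0.15).

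In input, which shows total RNA, the immediate early transcription factor EGR1 (2830861) rose 13.8-fold after 30 min of arsenite. Its log2 value went from 8.59 ± 0.07 to 12.37 ± 0.16 (SD, n = 3; adjusted p = 2.2e-12). The metallothionein MT1X, which binds heavy metals, rose by 2.45 ± 0.25 on the log2 scale, and ATF4, the transcription factor of the integrated stress response, by 2.12 ± 0.12. The iron store subunit FTL rose by 1.27 ± 0.20, the immediate early gene FOS by 1.13 ± 0.13, and the matrix genes VCAN and FN1 by 1.14 ± 0.20 and 1.07 ± 0.14. LONRF1, which encodes a RING finger protein, fell by 1.86 ± 0.27, and the Mediator gene MED13L fell by 1.45 ± 0.10. The IKK alpha gene CHUK fell by 1.39 ± 0.24, the Notch pathway ubiquitin ligase gene MIB1 fell by 1.37 ± 0.18, and RC3H2, a regulator of mRNA decay, fell by 1.36 ± 0.15. ZCCHC14 (-1.45 ± 0.14), KIF13A (-1.37 ± 0.22), RALGAPA2 (-1.37 ± 0.19), SBF2 (-1.36 ± 0.19) and PSD3 (-1.32 ± 0.28) fell too. ZNF208 (1.67 ± 0.36), OR2V2 (1.02 ± 0.25) and H2BC10 (0.98 ± 0.31) were called higher at stressed means of 4.80, 5.42 and 5.54, low on this scale.

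In stressed input, ubiquitin ligases and deubiquitinases were lower in 18 of 38 members and higher in 0 (1 higher and 28 lower adjusted over the list alone). CBL (-1.11 ± 0.11), USP7 (-1.03 ± 0.14) and UBE3B (-0.99 ± 0.11) were among them. The list had a median of -0.55, or -0.35 without both arrays that stand apart (camera adjusted p = 3.7e-06), and camera gave adjusted p = 1.9e-08, and adjusted p = 0.631 with an estimated correlation. Secreted and matrix genes were higher in 16 of 41 members and lower in 0 (21 higher and 0 lower adjusted over the list alone), LOXL2 (0.88 ± 0.07), TNC (0.90 ± 0.09) and THBS1 (0.69 ± 0.07) among them. Matrix genes had a camera adjusted p = 7.3e-17, and adjusted p = 0.129 with an estimated correlation. Immediate early genes were higher in 9 of 30 members and lower in 1 (10 higher and 1 lower adjusted over the list alone), including CCN1 (0.91 ± 0.10) and JUNB (0.74 ± 0.11). Their camera test gave adjusted p = 8.1e-10, and adjusted p = 0.146 with an estimated correlation.

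Apoptosis and p53 genes were lower in 7 of 29 members and higher in 0 (0 higher and 9 lower adjusted over the list alone) in stressed input, with BCL2L1 at -0.66 ± 0.09 and MDM2 at -0.78 ± 0.14. Camera for apoptosis genes gave adjusted p = 0.00507, and adjusted p = 0.71 with an estimated correlation. Apoptosis genes went from a median of -0.37 to -0.21 without both arrays that stand apart (camera adjusted p = 0.0135). C2H2 zinc finger genes were lower in 57 of 301 members and higher in 1 (1 higher and 65 lower adjusted over the list alone), and camera gave adjusted p = 0.00125, and adjusted p = 0.71 with an estimated correlation. The oxidative stress and metal list held MT1X and FTL, which rose, and SRXN1 (-0.52 ± 0.09) and TXNRD1 (-0.59 ± 0.10), which fell, and was not called (camera adjusted p = 0.289). Of the markers of cell types, astrocyte and glioma markers were higher in 4 of 18 members and lower in 0 (4 higher and 0 lower adjusted over the list alone), with camera adjusted p = 0.00195, and adjusted p = 0.42 with an estimated correlation. Myeloid markers were higher in 1 of 17 members and lower in 0 (1 higher and 0 lower adjusted over the list alone), with camera adjusted p = 0.00324, and adjusted p = 0.42 with an estimated correlation. The median of myeloid markers went from 0.12 to 0.066 without both arrays (camera adjusted p = 0.0458). Neuron, epithelial and blood markers were not called (camera adjusted p = 0.289, 0.0656 and 0.101).

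In total 554 transcript clusters rose and 2472 fell in input, so that increases made up 18.3% of the calls. That share was 34.3% after median centring, 39.4% after quantile normalization and 39.4% after cyclic loess. It was 32.7% with array weights and 34.5% without both arrays that stand apart. Without input_unstressed replicate 1 the count went from 3026 to 1903.

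**Figure D2:**
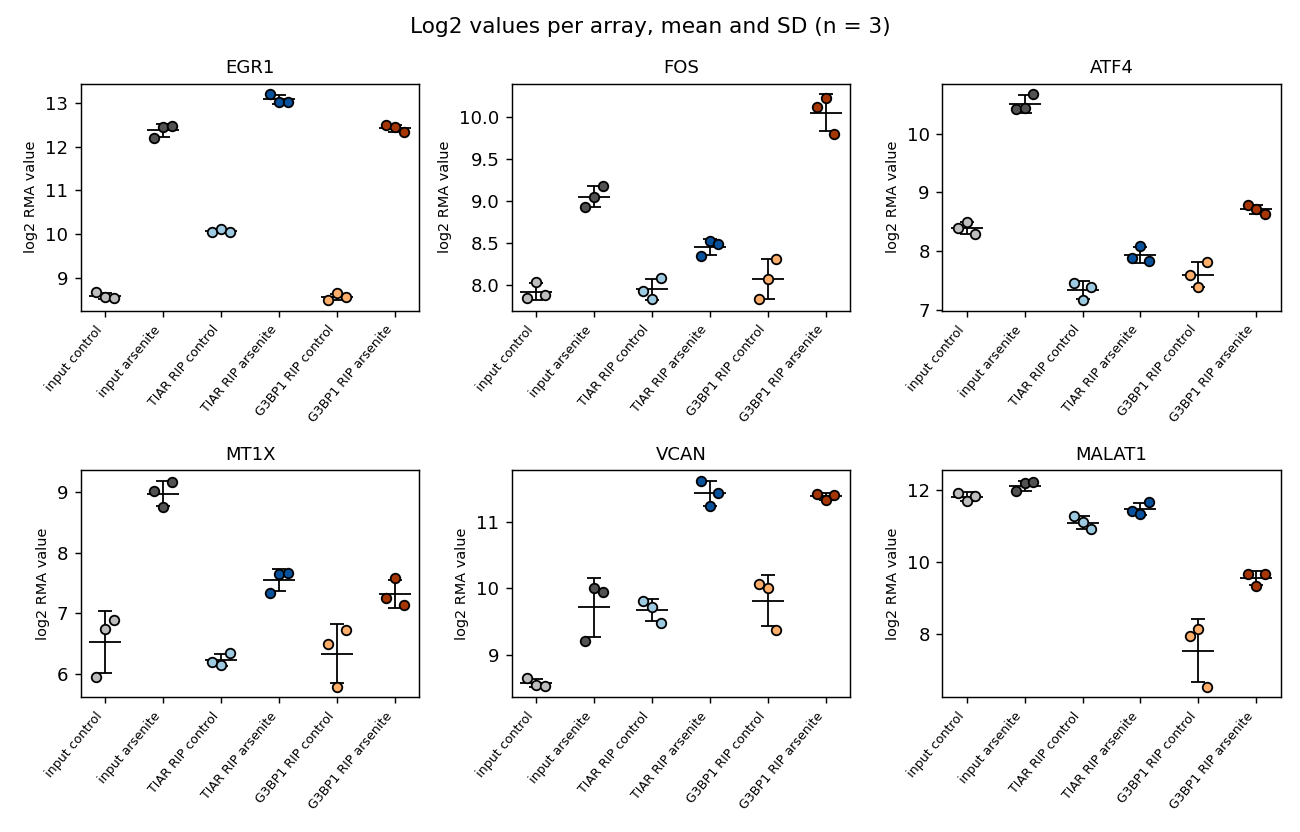
Log2 values of 6 genes on each array, with 1 point per array and the mean and SD of each group (n = 3). Mean EGR1 lay between 8.56 and 10.07 in the control groups and between 12.37 and 13.08 in the arsenite groups.

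In the TIAR RIP, EGR1 rose 8.07-fold with arsenite (log2 3.01 ± 0.09, adjusted p = 5.9e-11, n = 3 arrays per group). The matrix genes VCAN (1.75 ± 0.20), FN1 (1.67 ± 0.14) and ABI3BP (1.64 ± 0.21) rose, with ITGA2, which encodes a collagen receptor subunit (1.53 ± 0.23). The tRNA synthetase gene EPRS1 (1.74 ± 0.20), the centrosome scaffold gene AKAP9 (1.71 ± 0.26), the sulfatase gene ARSK (1.54 ± 0.33), SERINC1 (1.43 ± 0.23) and the RNA exosome gene EXOSC9 (1.44 ± 0.14) rose as well. BACH1, a repressor of haem oxygenase (-1.35 ± 0.16), fell, with ZFHX3 (-1.21 ± 0.07), ZBTB34 (-1.38 ± 0.20), ZSCAN29 (-1.30 ± 0.16), ZNF460 (-1.29 ± 0.19) and ZNF618 (-1.26 ± 0.20). LONRF1 (-1.45 ± 0.27), PSD3 (-1.40 ± 0.28), ZCCHC14 (-1.24 ± 0.14) and the myosin gene MYO9A (-1.22 ± 0.25) fell too.

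With arsenite in the TIAR RIP, secreted and matrix genes were higher in 21 of 41 members and lower in 0 (25 higher and 0 lower adjusted over the list alone). LOXL2 (1.01 ± 0.07), TNC (1.26 ± 0.09) and the chaperone gene CLU (1.02 ± 0.08) were among them. Their median was 0.30, and camera gave adjusted p = 8.8e-20, and adjusted p = 0.0759 with an estimated correlation. Endoplasmic reticulum genes were higher in 18 of 34 members and lower in 0 (19 higher and 0 lower adjusted over the list alone), such as the chaperone gene HSPA5 (1.22 ± 0.11) and the glycosylation gene STT3A (0.93 ± 0.08). For this list camera gave adjusted p = 5.7e-14, and adjusted p = 0.504 with an estimated correlation. Mitosis genes were higher in 17 of 42 members and lower in 2 (26 higher and 2 lower adjusted over the list alone), including ANLN (0.84 ± 0.12), TPX2 (0.68 ± 0.11) and CCNB1 (0.76 ± 0.14). Camera for mitosis genes gave adjusted p = 2.5e-11, and adjusted p = 0.608 with an estimated correlation. Splicing factors were higher in 13 of 37 members and lower in 0 (13 higher and 1 lower adjusted over the list alone), with PRPF3 at 1.08 ± 0.16. Their camera result was adjusted p = 1.1e-07, and adjusted p = 0.608 with an estimated correlation. Heat shock genes were higher in 8 of 17 members and lower in 0 (8 higher and 0 lower adjusted over the list alone), with HSPH1 at 0.87 ± 0.12. Camera on them gave adjusted p = 1.6e-05, and adjusted p = 0.504 with an estimated correlation.

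Glycolysis genes were higher in 7 of 18 members and lower in 1 (7 higher and 1 lower adjusted over the list alone) in the stressed TIAR RIP, with ENO1 at 1.13 ± 0.07. Camera gave adjusted p = 5.4e-05, and adjusted p = 0.608 with an estimated correlation. DNA replication genes were higher in 7 of 38 members and lower in 1 (7 higher and 1 lower adjusted over the list alone), with PRIM1 at 0.58 ± 0.10. The replication list had a camera adjusted p = 4.5e-05, and adjusted p = 0.66 with an estimated correlation. Proteasome genes were higher in 7 of 29 members and lower in 0 (8 higher and 0 lower adjusted over the list alone), with PSMC3 at 0.85 ± 0.12. Camera on the proteasome gave adjusted p = 2.9e-05, and adjusted p = 0.623 with an estimated correlation. C2H2 zinc finger genes were lower in 28 of 301 members and higher in 0 (0 higher and 28 lower adjusted over the list alone), with ZNF236 at -0.89 ± 0.10. The zinc finger list had a camera adjusted p = 5.4e-05, and adjusted p = 0.66 with an estimated correlation. Histone genes were not called (camera adjusted p = 0.229).

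In total 1353 transcript clusters rose and 1256 fell in the TIAR RIP. Without both arrays that stand apart these were 2561 and 2496. Neither of those arrays is in this comparison, so its log2 changes stayed the same and only the spread estimated over all groups moved.

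**Figure D3:**
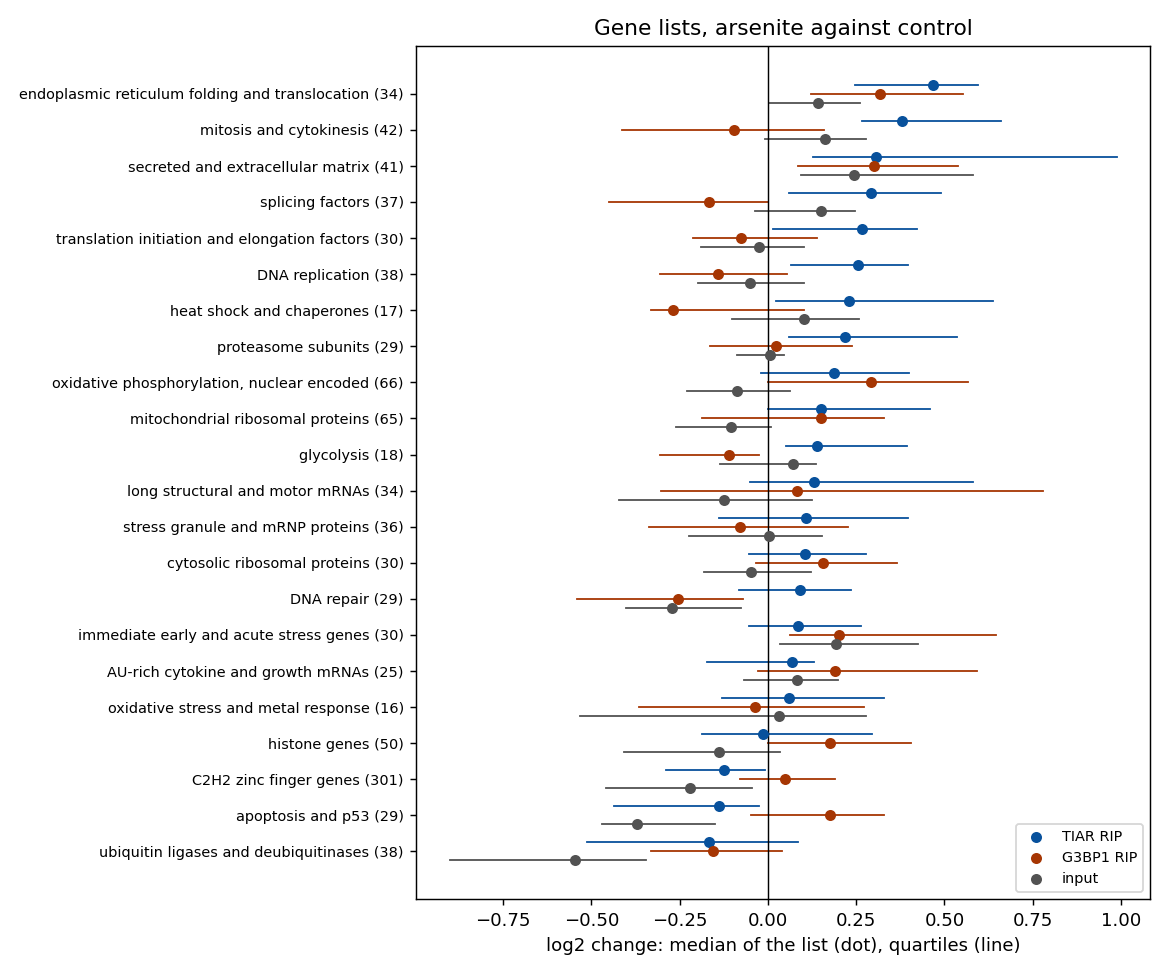
Median (dot) and quartiles (line) of the log2 change with arsenite over the members of each gene list shown, in the TIAR RIP, the G3BP1 RIP and input, with the number of members in brackets. Mitosis genes had a median of 0.38 in the TIAR RIP and -0.10 in the G3BP1 RIP.

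In the G3BP1 RIP, EGR1 rose by 3.86 ± 0.09 on the log2 scale with arsenite (adjusted p = 1.6e-12, n = 3 arrays per group) and FOS by 1.98 ± 0.13. MALAT1, a nuclear long noncoding RNA, rose by 2.03 ± 0.29, from 7.53 ± 0.88 to 9.56 ± 0.20 (SD), and the mitochondrially encoded complex I transcript ND5 by 1.54 ± 0.12. The cytoskeletal scaffold gene IQGAP1 rose by 1.71 ± 0.08, with VCAN (1.56 ± 0.20), AKAP9 (1.55 ± 0.26), the lipopolysaccharide coreceptor gene LY96 (1.54 ± 0.38), PPDPF (1.47 ± 0.12) and SFT2D2 (1.44 ± 0.21). SNW1, a spliceosome gene (-1.31 ± 0.16), HNRNPD, whose protein AUF1 binds AU-rich elements (-1.16 ± 0.11), and the RNA polymerase II gene POLR2B (-1.18 ± 0.19) fell. The DNA end joining gene XRCC4 (-1.47 ± 0.24), the cochaperone gene DNAJA2 (-1.29 ± 0.20), ZNHIT6 (-1.25 ± 0.33), C11orf54 (-1.22 ± 0.27), RPS10P7 (-1.21 ± 0.36) and GMPPB (-1.17 ± 0.13) fell too. EIF2S2 was called lower (-1.55 ± 0.39) at means of 4.22 and 2.66, low on this scale.

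With arsenite in the G3BP1 RIP, secreted and matrix genes were higher in 21 of 41 members and lower in 0 (24 higher and 1 lower adjusted over the list alone), with FN1 at 1.20 ± 0.14 and the protease inhibitor gene TIMP1 at 1.01 ± 0.12. Camera gave adjusted p = 1.4e-08, and adjusted p = 0.739 with an estimated correlation. Immediate early genes were higher in 12 of 30 members and lower in 1 (14 higher and 1 lower adjusted over the list alone), with CCN1 at 0.84 ± 0.10 and IER3 at 0.62 ± 0.08. For immediate early genes camera gave adjusted p = 3.4e-05, and adjusted p = 0.739 with an estimated correlation. Genes of AU-rich cytokine and growth mRNAs were higher in 9 of 25 members and lower in 0 (10 higher and 0 lower adjusted over the list alone), with LIF at 1.05 ± 0.10 and PLAUR at 0.67 ± 0.08. The AU-rich list had a camera adjusted p = 0.00371, and adjusted p = 0.93 with an estimated correlation. Endoplasmic reticulum genes were higher in 12 of 34 members and lower in 1 (17 higher and 1 lower adjusted over the list alone), with SYVN1 at 1.04 ± 0.08 and XBP1 at 0.74 ± 0.16. Their camera test gave adjusted p = 3.4e-05, and adjusted p = 0.93 with an estimated correlation. Oxidative phosphorylation genes were higher in 19 of 66 members and lower in 1 (28 higher and 2 lower adjusted over the list alone), with NDUFA7 at 0.87 ± 0.11. Camera on respiratory genes gave adjusted p = 1.9e-04, and adjusted p = 0.93 with an estimated correlation. The median of the respiratory list went from 0.29 to 0.14 without both arrays that stand apart, with 16 members higher and 7 lower (camera adjusted p = 0.0436).

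Splicing factors were lower in 11 of 37 members and higher in 1 (2 higher and 13 lower adjusted over the list alone) in the stressed G3BP1 RIP, with TRA2B at -0.62 ± 0.09 and SF3B2 at -0.45 ± 0.09. For splicing factors camera gave adjusted p = 1.5e-04, and adjusted p = 0.93 with an estimated correlation. DNA repair genes were lower in 3 of 29 members and higher in 0 (0 higher and 3 lower adjusted over the list alone), with TP53BP1 at -0.97 ± 0.16 beside XRCC4. The repair list had a camera adjusted p = 2.4e-04, and adjusted p = 0.93 with an estimated correlation. Mitosis genes were not called (camera adjusted p = 0.105), nor were astrocyte, neuron, myeloid, epithelial and blood markers (camera adjusted p = 0.431, 0.438, 0.998, 0.639 and 0.57).

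In total 2290 transcript clusters rose and 899 fell in the G3BP1 RIP, and increases made up 71.8% of the calls. That majority turned without both arrays that stand apart (2448 rose and 3016 fell, 44.8%) and with array weights (47.8%). The share was 58.3% after median centring, 55.5% after quantile normalization and 58.7% after cyclic loess.

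The RIPs shared part of their stress changes. EGR1, VCAN, AKAP9, ABI3BP and FN1 rose in both, and so did IQGAP1 (1.43 ± 0.08 in TIAR and 1.71 ± 0.08 in G3BP1), the microfibril gene FBN1 (1.32 ± 0.17 and 1.41 ± 0.17) and the lysine catabolism gene AASS (1.38 ± 0.19 and 1.20 ± 0.19). The collagen gene COL12A1 (1.27 ± 0.18 and 1.12 ± 0.18) and FOS (0.51 ± 0.13 and 1.98 ± 0.13) did as well. In all, 412 transcript clusters rose in both RIPs, where independent lists would share 140.8, and 85 fell in both (51.3). A further 264 fell in TIAR and rose in G3BP1 (130.7), and 165 did the reverse (55.3). Overlaps in opposite directions thus exceeded the number for independent lists too, so these counts do not show that the RIPs changed alike. Without both arrays that stand apart, the shared TIAR and G3BP1 stress changes went from 497 to 1173.

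Across transcript clusters, which are not independent replicates, the stress changes of the TIAR and G3BP1 RIPs correlated at r = 0.067 (Spearman 0.004). The changes of the TIAR RIP and input correlated at r = 0.494 (Spearman 0.415), with 306 transcript clusters higher in both (34.1 if independent) and 973 lower in both (141.1). The changes of the G3BP1 RIP and input correlated at r = -0.016 (Spearman -0.078). Even so, 154 transcript clusters were higher in both (57.6 if independent) and 157 lower in both, which is also more than independent lists would share. Overlaps in opposite directions are not given for the pairs with input.

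The TIAR stress-granule set held 385 transcript clusters that rose with arsenite in the TIAR RIP and were higher there than in stressed input. The comparisons share the stressed TIAR arrays, which gave r = 0.5 across transcript clusters in simulated unchanged groups. The measured r was -0.21, and transcript clusters are not independent replicates. The set included TFPI, which encodes a coagulation inhibitor (1.13 ± 0.26 with stress and 2.67 ± 0.26 over input), ABI3BP (1.64 and 2.11), EGR1 (3.01 and 0.71), VCAN (1.75 and 1.71) and ARSK (1.54 and 1.80). CD109 (1.35 and 1.92), ITGA2 (1.53 and 1.68), PLBD2 (0.89 and 2.19), the oncostatin M receptor gene OSMR (0.88 and 2.18) and the R-spondin receptor gene LGR5 (0.71 and 2.34) followed. Membership does not mean a rise beyond that of input. EGR1 was 1.49 over input without stress, and its stress change beyond input was -0.77. The count went to 225 without TIAR_stressed replicate 1, 254 without TIAR_stressed replicate 3 and 239 without TIAR_unstressed replicate 3, and to 726 without both arrays that stand apart.

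The G3BP1 stress-granule set held 1271 transcript clusters. Its comparisons share the stressed G3BP1 arrays (r = 0.495 in simulated unchanged groups, and -0.069 measured). The set included FBN1 (1.41 ± 0.17 with stress and 2.57 ± 0.17 over input), the cadherin genes FAT1 (1.35 and 2.37) and FAT4 (0.80 and 2.43), FRAS1 (1.25 and 2.42), the glypican gene GPC6 (1.11 and 2.35) and the laminin gene LAMA1 (1.09 and 2.26). HMCN1 (1.05 and 2.13), the activin binding protein gene FST (0.68 and 2.58), VCAN (1.56 and 1.66) and the motor gene DYNC1H1 (0.98 and 2.67) were also in it. The count went to 779 without G3BP1_stressed replicate 1 and 828 without G3BP1_stressed replicate 2.

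Both sets held 127 transcript clusters, and both rest on the same stressed input arrays, so no number for unrelated sets is given. ABI3BP, VCAN, FBN1, FAT1, COL12A1, FRAS1 and LGR5 were among them, beside YLPM1 (0.86 ± 0.19 in TIAR and 1.40 ± 0.19 in G3BP1 with stress), the class III PI3K subunit gene PIK3R4 (0.99 and 0.65) and the carboxypeptidase gene CPD (0.84 and 0.76). ECT2 and AURKB were in neither set, since neither was called above stressed input in a RIP.

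The stress change of the TIAR RIP was tested against that of input. EXOSC9 (1.23 ± 0.20, adjusted p = 0.0196), the calcium-binding protein gene S100A13 (1.18 ± 0.24), the cochaperone gene DNAJC7 (1.17 ± 0.14), AATF, which encodes a ribosome biogenesis factor (1.15 ± 0.13), and the guanine nucleotide synthesis gene IMPDH2 (1.15 ± 0.21) rose relative to input. Their means in the stressed TIAR RIP still lay below those in stressed input. EXOSC9 had 9.23 against 10.99, S100A13 8.73 against 11.46 and DNAJC7 9.34 against 10.36. AATF had 8.91 against 10.74 and IMPDH2 10.53 against 11.26. ATF4 had a lower change, by -1.52 ± 0.17 (adjusted p = 0.00227): it went from 8.39 to 10.51 in input and from 7.34 to 7.93 in the TIAR RIP. EGR1 (-0.77 ± 0.13), ANKRD49 (-1.30 ± 0.22), PBDC1 (-0.87 ± 0.15) and, at low signal, ZBTB7C-AS2 (-1.03 ± 0.22) also had lower changes. Immediate early genes were lower in 1 of 30 members and higher in 0 (0 higher and 1 lower adjusted over the list alone), and camera gave adjusted p = 1.9e-06, and adjusted p = 0.7 with an estimated correlation. Ubiquitin ligases were higher in 0 of 38 members and lower in 0 (2 higher and 0 lower adjusted over the list alone), with a median of 0.40. For ubiquitin ligases camera gave adjusted p = 2.2e-04, and adjusted p = 0.7 with an estimated correlation. The median of that list was 0.24 without both arrays that stand apart (camera adjusted p = 0.0321).

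In total 133 transcript clusters were higher and 11 lower for the TIAR stress change beyond input, with 2826 at an unadjusted p under 0.05. Increases made up 92.4%, or 79.1% after median centring, 73.6% after quantile normalization and 82.8% after cyclic loess, and 81.1% without both arrays that stand apart (594 higher and 138 lower). The count of 144 rested on single arrays. It went to 33, 50 and 76 without TIAR_stressed replicates 1, 2 and 3, and to 50, 15 and 40 without TIAR_unstressed replicates 1, 2 and 3. Without input_stressed replicate 1 it went to 63, and without input_unstressed replicates 1, 2 and 3 to 20, 20 and 25.

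In the G3BP1 RIP, LRRC8B, which encodes an anion channel subunit (2.07 ± 0.34, adjusted p = 7.1e-04), the O-mannose kinase gene POMK (2.02 ± 0.23), TMTC1 (1.99 ± 0.32), the tubulin carboxypeptidase cofactor gene SVBP (2.05 ± 0.58) and, at low signal, the noncoding RNA JPX (2.13 ± 0.51) rose relative to input. The mean of each of them also fell in input, which is part of these values. SVBP went from 8.49 ± 0.87 to 9.56 ± 0.14 (SD) in the RIP and from 9.84 ± 0.14 to 8.86 ± 0.98 in input. JPX went from 4.88 ± 0.48 to 5.91 ± 0.35 and from 6.97 ± 0.38 to 5.86 ± 0.82. The spliceosome genes IK (-1.77 ± 0.23, adjusted p = 1.4e-04) and SNW1 (-1.53 ± 0.22), the dynein gene DYNC1I2 (-1.65 ± 0.28), DNAJA2 (-1.49 ± 0.28) and FUBP1, a regulator of MYC (-1.48 ± 0.20), fell relative to input. Splicing factors were lower in 7 of 37 members and higher in 0 (0 higher and 8 lower adjusted over the list alone), with a median of -0.35. For splicing factors camera gave adjusted p = 7.9e-07, and adjusted p = 0.821 with an estimated correlation. Apoptosis and p53 genes were higher in 12 of 29 members and lower in 0 (15 higher and 1 lower adjusted over the list alone), among them MDM2 (1.07 ± 0.19), BCL2L1 (0.84 ± 0.13) and BAX (0.93 ± 0.23). Camera on apoptosis genes gave adjusted p = 0.0347, and adjusted p = 0.821 with an estimated correlation. This list depended on the arrays that stand apart: without both, its median went from 0.53 to 0.23, with 8 members higher and 3 lower, and it was not called (camera adjusted p = 0.285). In total 3137 transcript clusters were higher and 584 lower (84.3% higher). That share was 65.9% after median centring, 61.2% after quantile normalization and 63.1% after cyclic loess, 60.4% with array weights and 57.3% without both arrays that stand apart, and median centring moved the median of all changes from 0.05 to -0.10.

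The stress changes of the RIPs were tested against each other. EXOSC9 (2.29 ± 0.20, adjusted p = 9.0e-06), AATF (1.86 ± 0.13), IK (2.15 ± 0.23), SSB, whose protein La binds RNA polymerase III transcripts (1.92 ± 0.22), the kinetochore motor gene CENPE (1.87 ± 0.50) and G3BP1 (0.73 ± 0.18) had higher changes in the TIAR RIP. POMK (-2.04 ± 0.23), LINC00052 (-1.90 ± 0.27), PLAGL2 (-1.82 ± 0.24), TAX1BP3 (-1.81 ± 0.43) and EI24 (-1.75 ± 0.33) had higher changes in the G3BP1 RIP. Splicing factors were higher in 16 of 37 members and lower in 0 (21 higher and 2 lower adjusted over the list alone) in TIAR, SRSF11 (0.93 ± 0.15) among them. Camera for splicing factors gave adjusted p = 3.7e-11, and adjusted p = 0.73 with an estimated correlation. Mitosis genes were higher in 14 of 42 members and lower in 1 (19 higher and 2 lower adjusted over the list alone), NDC80 (1.51 ± 0.28) among them. The mitosis list had a camera adjusted p = 9.8e-10, and adjusted p = 0.73 with an estimated correlation. Heat shock genes were higher in 8 of 17 members and lower in 0 (10 higher and 1 lower adjusted over the list alone), HSPH1 (1.61 ± 0.17) among them. For heat shock genes camera gave adjusted p = 1.0e-05, and adjusted p = 0.73 with an estimated correlation. Immediate early genes were lower in 5 of 30 members and higher in 0 (0 higher and 5 lower adjusted over the list alone), FOS (-1.47 ± 0.18) among them. Camera on immediate early genes gave adjusted p = 0.0305, and adjusted p = 0.73 with an estimated correlation. Their median went from -0.22 to -0.15 without both arrays that stand apart, where they were not called (camera adjusted p = 0.0857).

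In total 1112 transcript clusters had a higher and 1882 a lower stress change in the TIAR than in the G3BP1 RIP (37.1% higher). That share was 49.7% after cyclic loess, 52.9% with array weights and 54.3% without both arrays that stand apart (2955 higher and 2492 lower).

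Against input, the stressed TIAR RIP held more LMLN, a peptidase gene (2.94 ± 0.20), DENND1B (2.73 ± 0.20), PGAP1 (2.69 ± 0.38), TFPI (2.67 ± 0.26), the TAK1 adaptor gene TAB2 (2.56 ± 0.18), the cytokine receptor gene LIFR (2.53 ± 0.30), TLCD4 (2.51 ± 0.18) and the peroxisomal transporter gene ABCD3 (2.50 ± 0.27). It held less of the histone mRNAs H2BC3 (-3.94 ± 0.59), H3C1 (-3.21 ± 0.32) and H1-5 (-3.15 ± 0.37), and of the respiratory chain genes NDUFA1 (-3.32 ± 0.27), COX7A2 (-2.92 ± 0.49) and UQCC2 (-3.21 ± 0.23). The prefoldin gene PFDN5 (-3.11 ± 0.31) and the proteasome gene PSMB3 (-2.97 ± 0.18) were low as well. Without stress, LMLN (2.56 ± 0.20), NREP (2.49 ± 0.18), DENND1B (2.42 ± 0.20), TFPI (2.41 ± 0.26) and BBOF1 (2.39 ± 0.20) were higher than input, and H1-5 (-4.40 ± 0.37), H2BC3 (-4.00 ± 0.59), S100A13 (-3.90 ± 0.17), NDUFA1 (-3.90 ± 0.27) and H2BC4 (-3.86 ± 0.43) lower. Across transcript clusters, the differences from input with and without stress correlated at r = 0.893 (Spearman 0.83).

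Without stress, histone genes were lower in 44 of 50 members and higher in 0 (0 higher and 45 lower adjusted over the list alone) in the TIAR RIP against input, with a median of -1.57. Camera gave adjusted p = 3.6e-16, and adjusted p = 0.447 with an estimated correlation. Oxidative phosphorylation genes were lower in 52 of 66 members and higher in 1 (1 higher and 53 lower adjusted over the list alone), with NDUFB10 at -3.31 ± 0.13. For respiratory genes camera gave adjusted p = 1.3e-16, and adjusted p = 0.447 with an estimated correlation. Mitochondrial ribosomal protein genes were lower in 52 of 65 members and higher in 1 (2 higher and 53 lower adjusted over the list alone), with MRPL46 at -3.17 ± 0.09. Their camera test gave adjusted p = 1.3e-16, and adjusted p = 0.565 with an estimated correlation. Cytosolic ribosomal protein genes were lower in 22 of 30 members and higher in 1 (1 higher and 24 lower adjusted over the list alone), with RPS14 at -2.59 ± 0.17. The ribosomal list had a camera adjusted p = 8.0e-08, and adjusted p = 0.447 with an estimated correlation. Translation factors were lower in 21 of 30 members and higher in 2 (2 higher and 21 lower adjusted over the list alone), with EIF3G at -2.55 ± 0.11. Camera on translation factors gave adjusted p = 4.2e-06, and adjusted p = 0.705 with an estimated correlation.

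Ubiquitin ligases were higher in 23 of 38 members and lower in 4 (24 higher and 4 lower adjusted over the list alone) in the unstressed TIAR RIP against input, with RNF111 at 2.10 ± 0.18. For ubiquitin ligases camera gave adjusted p = 2.3e-05, and adjusted p = 0.857 with an estimated correlation. Genes of stress granule and mRNP proteins were higher in 21 of 36 members and lower in 7 (21 higher and 8 lower adjusted over the list alone), with the decapping helicase gene DDX6 at 1.28 ± 0.11. The mRNP list had a camera adjusted p = 0.00906, and adjusted p = 0.942 with an estimated correlation. In total 4468 transcript clusters were higher and 5178 lower than input with stress (46.3% higher, and 34.2% with a floor on low values). Without stress 3693 were higher and 5242 lower (41.3% higher). That share was 56.9% after median centring, which moved the median of all differences from -0.05 to 0.12, 55.2% after quantile normalization and 29.9% with the floor.

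**Figure D4:**
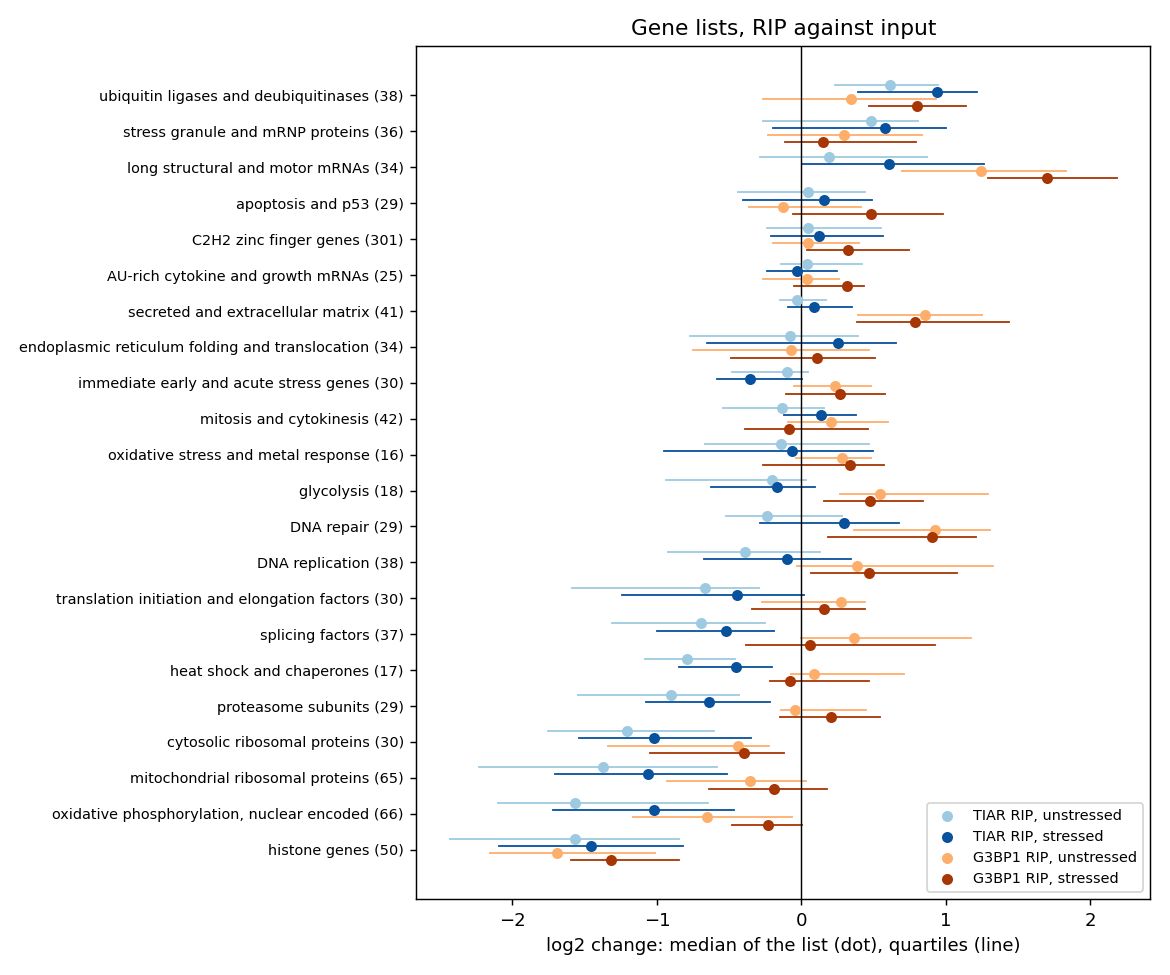
Median (dot) and quartiles (line) of the log2 difference between RIP and input over the members of each gene list shown, for each antibody with and without arsenite, with the number of members in brackets. Histone genes had medians from -1.69 to -1.32.

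The stressed G3BP1 RIP held more HERC1 (2.85 ± 0.19), DYNC1H1 (2.67 ± 0.12), UBR4 (2.47 ± 0.14) and the DNA-dependent protein kinase gene PRKDC (2.46 ± 0.17) than input. The diacylglycerol kinase gene DGKA (2.71 ± 0.09), FST (2.58 ± 0.16), FBN1 (2.57 ± 0.17) and PIK3R4 (2.44 ± 0.18) were also high. MALAT1 (-2.57 ± 0.29), the histone mRNAs H2BC3 (-2.37 ± 0.59), H2AC15 (-2.30 ± 0.17), H4C9 (-2.25 ± 0.24), H3C1 (-2.08 ± 0.32) and H4C1 (-1.95 ± 0.28), the small GTPase gene RAP1B (-2.13 ± 0.72) and XAF1 (-2.02 ± 0.27) were lower. Without stress, DGKA (2.52 ± 0.09), SMARCA1 (2.52 ± 0.19), the spliceosome helicase gene SNRNP200 (2.39 ± 0.11), UTP20 (2.36 ± 0.19) and URGCP (2.33 ± 0.26) were higher than input. MALAT1 (-4.29 ± 0.29), H2BC3 (-3.94 ± 0.59), COMMD6 (-3.70 ± 0.32), TMEM258 (-3.33 ± 0.21) and COX7A2 (-3.32 ± 0.49) were lower. G3BP1 mRNA was higher than input in the unstressed G3BP1 RIP (0.80 ± 0.13, adjusted p = 1.1e-04), and its value with stress was 0.03 ± 0.13 (adjusted p = 0.879).

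With stress, long structural and motor genes were higher in 32 of 34 members and lower in 1 (32 higher and 1 lower adjusted over the list alone) in the G3BP1 RIP against input, with a median of 1.70 and MYH9 at 1.41 ± 0.07. Camera gave adjusted p = 3.0e-12, and adjusted p = 0.671 with an estimated correlation. Secreted and matrix genes were higher in 33 of 41 members and lower in 0 (34 higher and 1 lower adjusted over the list alone), with TNC at 1.56 ± 0.09. For matrix genes camera gave adjusted p = 1.9e-09, and adjusted p = 0.346 with an estimated correlation. Histone genes were lower in 47 of 50 members and higher in 0 (0 higher and 48 lower adjusted over the list alone), with a median of -1.32. The histone list had a camera adjusted p = 5.7e-27, and adjusted p = 0.346 with an estimated correlation. Without stress, splicing factors were higher in 19 of 37 members and lower in 3 (19 higher and 3 lower adjusted over the list alone), with PRPF8 at 1.92 ± 0.08. Camera on splicing factors gave adjusted p = 6.8e-04, and adjusted p = 0.946 with an estimated correlation. In total 6440 transcript clusters were higher and 3339 lower with stress (65.9% higher). That share was 48.9% after median centring, which moved the median of all differences from 0.03 to -0.14, 52% after cyclic loess and 49% with a floor. Without stress 4546 were higher and 4219 lower (51.9% higher, and 37.8% with the floor).

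Differences of the TIAR and G3BP1 RIPs from input share the input arrays. Simulated unchanged groups gave a correlation of 0.497 with stress and 0.499 without, across transcript clusters, which are not independent replicates. The measured values were r = 0.42 (Spearman 0.378) and r = 0.23 (Spearman 0.159). The covariance was 0.207 with stress, against 0.0188 in the simulations, and 0.125 without, against 0.0189.

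Without stress the TIAR RIP held more LYPLA1, a thioesterase gene (4.18 ± 0.40), NREP (4.16 ± 0.18), LINC00052 (3.77 ± 0.19), TLCD4 (3.74 ± 0.18) and MMD (3.58 ± 0.12) than the G3BP1 RIP. It held less of the proteasome gene PSMC3 (-4.03 ± 0.12), AATF (-3.82 ± 0.09), EXOSC9 (-3.72 ± 0.14), the mitochondrial peptidase gene PMPCB (-3.69 ± 0.22) and AIFM1 (-3.66 ± 0.18). With stress LYPLA1 (3.37 ± 0.40), TLCD4 (2.90 ± 0.18), TFPI (2.71 ± 0.26), the thrombin receptor gene F2RL2 (2.63 ± 0.24) and NREP (2.51 ± 0.18) were higher in the TIAR RIP. NSMCE1 (-3.33 ± 0.31), NDUFB7 (-3.31 ± 0.21), the snurportin gene SNUPN (-3.29 ± 0.25), PSMC3 (-3.21 ± 0.12) and UQCC2 (-3.15 ± 0.23) were lower. AURKB was lower in the TIAR RIP without stress (-1.01 ± 0.08) and with it (-0.92 ± 0.08), and ECT2 without stress (-0.72 ± 0.25, adjusted p = 0.0261).

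Without stress, splicing factors were lower in 32 of 37 members and higher in 1 (1 higher and 33 lower adjusted over the list alone) in the TIAR RIP against the G3BP1 RIP, with SNRNP70 at -3.05 ± 0.11. Camera gave adjusted p = 1.8e-08, and adjusted p = 0.846 with an estimated correlation. Secreted and matrix genes were lower in 31 of 41 members and higher in 1 (1 higher and 32 lower adjusted over the list alone), with CLU at -1.98 ± 0.08. For matrix genes camera gave adjusted p = 7.7e-08, and adjusted p = 0.846 with an estimated correlation. In total 4256 transcript clusters were higher and 6054 lower without stress (41.3% higher). That share was 54.4% after median centring, 48.7% after quantile normalization and 48.2% after cyclic loess, and 54.9% with a floor on low values. With stress 3440 were higher and 6312 lower (35.3% higher), a share of 54.5% after median centring, 47.3% after quantile normalization and 48.1% after cyclic loess, and of 51.5% with the floor. Median centring moved the median of all differences from -0.05 to 0.14 without stress and from -0.05 to 0.17 with it.

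**Figure D5:**
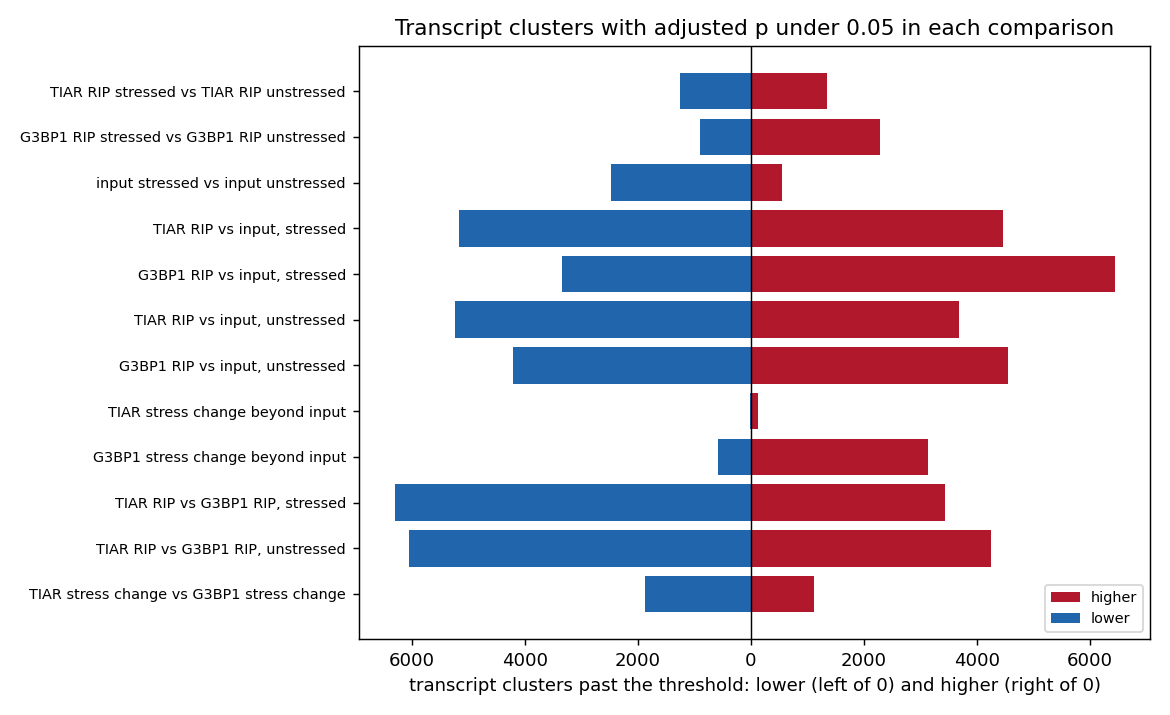
Number of transcript clusters with adjusted p under 0.05 in each of the 12 comparisons, with lower ones to the left of 0 and higher ones to the right. The counts run from 144 (TIAR stress change beyond input) to 10310 (TIAR RIP against G3BP1 RIP without stress).

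Across the 12 comparisons 158 list results were called by camera with the preset correlation, and 0 with an estimated correlation on all arrays, while fry called from 0 to 20 of the 28 lists per comparison. Glycolysis genes in the TIAR RIP beyond input were the 1 called list whose median changed sign under a scaling (0.15, and -0.01 after quantile normalization).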

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

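The tests without both arrays that stand apart, under other scalings and across the G3BP1 RIP and input were chosen only after the result was seen; the counts over other splits and the tests of the axis within groups were planned. The values below stood out because the stress change differed between RIP and input, or between the RIPs, in a test of that difference.

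144 transcript clusters passed for the TIAR stress change beyond input: EXOSC9 (1.23), S100A13 (1.18), DNAJC7 (1.17), AATF (1.15) and IMPDH2 (1.15) had higher changes, and ATF4 (-1.52), ANKRD49 (-1.30), ZBTB7C-AS2 (-1.03), PBDC1 (-0.87) and EGR1 (-0.77) lower ones. Of 100 drawn splits of the 12 arrays, 5 gave as many calls, the real one included, which is not under a share of 0.05. The highest other split called 1114, several times the real count. In each of the 4 other splits with as many calls, 6 of 6 TIAR arrays kept their arsenite label and 2 of 6 input arrays did. The structure these splits point to is thus arsenite treatment in the TIAR RIP, which they set against a mixture in input. They carry a real change, so they neither exclude chance nor show that chance gives as many calls, and a hidden grouping was not tested.

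3721 passed for the G3BP1 stress change beyond input. JPX (2.13), LRRC8B (2.07), SVBP (2.05), POMK (2.02) and TMTC1 (1.99) had higher changes, and IK (-1.77), DYNC1I2 (-1.65), SNW1 (-1.53), DNAJA2 (-1.49), FUBP1 (-1.48) and G3BP1 (-0.77) lower ones. Of 100 drawn splits 1, the real one, gave as many, which argues against chance without excluding it. The highest other called 1778, and in it 4 of 6 G3BP1 arrays and 6 of 6 input arrays kept their arsenite label. A hidden grouping was not tested.

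2994 passed for the difference between the stress changes of the RIPs. EXOSC9 (2.29), IK (2.15), SSB (1.92), CENPE (1.87), AATF (1.86) and G3BP1 (0.73) had higher changes in TIAR, and POMK (-2.04), LINC00052 (-1.90), PLAGL2 (-1.82), TAX1BP3 (-1.81) and EI24 (-1.75) in G3BP1. Of 100 drawn splits 1, the real one, gave as many, which is under a share of 0.05. This too argues against chance without excluding it. The highest other called 926, and in it 4 of 6 TIAR arrays and 6 of 6 G3BP1 arrays kept their arsenite label. A hidden grouping was not tested. Lists called by camera for this difference had medians of 0.53 (heat shock), 0.52 (splicing factors), 0.49 (mitosis), 0.38 (glycolysis), 0.37 (translation factors), 0.37 (DNA replication) and 0.30 (DNA repair). Smaller medians were 0.19 (proteasome), 0.14 (mRNP proteins), 0.10 (matrix), 0.039 (endoplasmic reticulum), -0.18 (zinc fingers), -0.22 (immediate early genes), -0.23 (AU-rich mRNAs) and -0.31 (apoptosis). Of these 15 lists 0 were called with an estimated correlation (lowest adjusted p = 0.73 with an estimated correlation), and fry called 5 lists. Not called without both arrays that stand apart were zinc fingers (-0.098, camera adjusted p = 0.134), immediate early genes (-0.15, camera adjusted p = 0.0857), AU-rich mRNAs (-0.13, camera adjusted p = 0.0526) and apoptosis genes (-0.14, camera adjusted p = 0.134).

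LRRC8B, POMK and the other genes that rose in the G3BP1 RIP beyond input had a median change of 0.83, and IK, SNW1 and the others that fell had -0.68. Without both arrays that stand apart the medians were 0.60 and -0.81, which argues against these arrays as the whole cause of either direction. The share of increases was 57.3% without both arrays and 84.3% with them, so these arrays may account for most of that excess. After the main axis of spread within groups was taken out, the median of the risers was 0.69, which argues against that axis as the whole cause. Jointly under all 3 scalings, 72% of the risers were called in the same direction, between the bounds set for the test. Of the fallers 92.3% were. Each of these scalings shifts changes downward and so favours the fallers, so scaling stays open for both. Stress-dependent binding to G3BP1, the biological difference the design names, stays open and untested.

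Stress changes of the TIAR RIP and input, among them those of EGR1, VCAN and FN1, ran together across transcript clusters (r = 0.494), which are not independent replicates. Without both arrays that stand apart r was 0.547, and 0.555 after the axis within groups was taken out, which argues against both as the cause. If a change of total RNA entered every RIP alike, the G3BP1 RIP would follow input too, but r between them was 0.085 without both arrays. This argues against such a change as the cause across all transcript clusters. On all arrays, though, 154 transcript clusters rose in both the G3BP1 RIP and input and 157 fell in both. Each count exceeds that of independent lists. Overlaps in opposite directions are not given for this pair, so the counts do not show that the G3BP1 RIP and input changed alike. Still, EGR1, VCAN and FN1 rose in the G3BP1 RIP too. For such genes a change of total RNA carried into both RIPs stays open. Input-like RNA carried over in the TIAR RIP alone, or binding that follows abundance, may be a cause, and no test here separates these.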

How the results depend on the processing

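The setting without both arrays that stand apart was chosen only after the result was seen; the others were planned. The counts of calls below moved by more than 1.5 times, and the cause was not tested except where given.

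With the replicate number as a block (replicate block) the count for the TIAR stress change beyond input was 55, from 144; the other 14 counts stayed within 1.5 times. Of 45 pairs of arrays with equal replicate number, 14 had residuals that correlated above 0.1 (-0.405 to 0.416, mean -0.015, and 0.009 for unequal numbers), so the numbers gave no sign of pairing. A fit of the compared groups alone, which has fewer arrays to estimate the spread, gave 866 (G3BP1 RIP stressed vs G3BP1 RIP unstressed), 1487 (input stressed vs input unstressed), 290 (G3BP1 stress-granule set) and 207 (shared TIAR and G3BP1 stress changes).

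Array weights gave 5485 (TIAR RIP stressed vs TIAR RIP unstressed), 6489 (G3BP1 RIP stressed vs G3BP1 RIP unstressed), 5328 (input stressed vs input unstressed), 1472 (TIAR stress change beyond input), 5960 (G3BP1 stress change beyond input), 6349 (TIAR stress change vs G3BP1 stress change), 863 (TIAR stress-granule set) and 1354 (shared TIAR and G3BP1 stress changes). Without both arrays that stand apart the counts were 5057, 5464, 732, 5447, 726 and 1173 for TIAR RIP stressed vs TIAR RIP unstressed, G3BP1 RIP stressed vs G3BP1 RIP unstressed, TIAR stress change beyond input, TIAR stress change vs G3BP1 stress change, TIAR stress-granule set and shared TIAR and G3BP1 stress changes. For TIAR RIP stressed vs TIAR RIP unstressed, which holds neither array, only the spread estimated over all groups moved.

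For the TIAR stress change beyond input the count was 219 with the lowest 25% of transcript clusters by mean left out, 312 with the lower 50% left out, 239 after quantile normalization, 325 after cyclic loess and 342 with a floor. The TIAR stress-granule set held 621, 629 and 683 after median centring, quantile normalization and loess, and the shared TIAR and G3BP1 stress changes 808, 925 and 916. Quantile normalization gave 3957 for TIAR RIP stressed vs TIAR RIP unstressed. With 1 transcript cluster per gene, which tests fewer, G3BP1 RIP vs input, unstressed gave 5677. In array structure, the lowest mean correlation with group mates went from 0.9799 to 0.9578 with the lower 50% left out.

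A minimum change of 2-fold, stricter by construction (2-fold threshold), gave 242 (TIAR RIP stressed vs TIAR RIP unstressed), 337 (G3BP1 RIP stressed vs G3BP1 RIP unstressed), 221 (input stressed vs input unstressed), 3378 (TIAR RIP vs input, stressed), 3132 (G3BP1 RIP vs input, stressed), 3304 (TIAR RIP vs input, unstressed), 3090 (G3BP1 RIP vs input, unstressed), 25 (TIAR stress change beyond input), 1143 (G3BP1 stress change beyond input), 4048 (TIAR RIP vs G3BP1 RIP, stressed), 4942 (TIAR RIP vs G3BP1 RIP, unstressed) and 800 (TIAR stress change vs G3BP1 stress change). It left 31 in the TIAR stress-granule set, 37 in the G3BP1 stress-granule set and 22 shared TIAR and G3BP1 stress changes.

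Leaving out 1 array at a time, the TIAR stress change beyond input ran from 15 to 124, the TIAR stress-granule set from 225 to 433, the G3BP1 stress-granule set from 779 to 1354 and input stressed vs input unstressed from 1903 to 2957. The other 11 counts stayed within 1.5 times.

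Of 294 results for named genes, 288 kept direction and call with the block, 272 with the compared groups alone, 285 with the floor, 253 with the 2-fold minimum and 276 without both arrays. EIF2S2: G3BP1 RIP stressed vs G3BP1 RIP unstressed reversed with the floor (0.035), which its own low signal explains by construction. Values near background limit what such genes show.

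Of 336 gene list results, 334 kept direction and call with the block, 323 after median centring, 314 with the lowest 25% left out, 302 without both arrays, 231 with fry and 178 with an estimated correlation. Camera with an estimated correlation called 0 lists in each of the 12 comparisons, where the preset called from 10 to 19 and fry, directional called 8 (TIAR RIP stressed vs TIAR RIP unstressed), 3 (G3BP1 RIP stressed vs G3BP1 RIP unstressed), 4 (input stressed vs input unstressed), 16 (TIAR RIP vs input, stressed), 17 (G3BP1 RIP vs input, stressed), 14 (TIAR RIP vs input, unstressed), 16 (G3BP1 RIP vs input, unstressed), 0 (TIAR stress change beyond input), 0 (G3BP1 stress change beyond input), 20 (TIAR RIP vs G3BP1 RIP, stressed), 20 (TIAR RIP vs G3BP1 RIP, unstressed) and 5 (TIAR stress change vs G3BP1 stress change). Leaving out both arrays that stand apart, camera with an estimated correlation called 1 list for TIAR RIP stressed vs TIAR RIP unstressed (matrix genes, adjusted p = 0.00667), 2 for input stressed vs input unstressed (matrix genes, 0.0044, and astrocyte markers, 0.0306) and 1 for G3BP1 RIP vs input, unstressed (matrix genes, 0.0461). With the lowest 25% left out, camera called 5 lists for the G3BP1 stress change beyond input. A correction of the lists for transcript length or GC content was not run, because no transcript sequences were at hand.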

Other observations

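The tests of short RNAs and of gene families were chosen only after the result was seen; the counts over other splits were planned. Transcript clusters with no gene symbol numbered 5171. With arsenite 363 of them were higher and 95 lower in the TIAR RIP, 325 and 223 in the G3BP1 RIP, and 213 and 252 in input. Against stressed input 470 were higher and 1313 lower in the TIAR RIP, and 638 and 1641 in the G3BP1 RIP.

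Histone mRNAs such as H2BC3 and respiratory chain mRNAs such as NDUFA1 were low against input in the TIAR RIP. These genes encode small proteins, so a loss of short RNAs that is equal in both RIPs is a candidate explanation. The test asked for a median TIAR minus G3BP1 difference within 0.5 of 0 without stress, a margin set for it. Mitochondrial ribosomal protein mRNAs had -1.05 (-1.33 to -0.58, 95% bootstrap interval), beyond the margin, which argues against an equal loss for them. Histone mRNAs had -0.083 (-0.26 to 0.077), which an equal loss would give, and oxidative phosphorylation mRNAs had -0.72 (-0.90 to -0.35), which lies away from 0 but reaches inside the margin. An exactly equal loss is not what they show, and a nearly equal one stays open.

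FBN1, FAT1, COL12A1 and VCAN, which encode matrix or cell surface proteins, rose in both RIPs. Families of membrane and secreted proteins, defined by symbol after the genes of both sets were seen, made up 22 of 111 genes in both sets (19.8%, against 5.5% of all genes). Their odds ratio was 4.33 (2.57 to 7.01), with 3.3 in the TIAR set and 2.96 in the G3BP1 set, across genes, which are not independent replicates. Single-pass and secreted families had 8.6 (4.47 to 15.4) and multi-pass families 1.99 (0.833 to 4.1). These ratios describe the sets and cannot support over-representation, because the families were chosen from the same genes.

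A second test asked whether multi-pass families move with single-pass families in the TIAR RIP. Their median stress changes were 0.009 (-0.009 to 0.023) and 0.031 (0.004 to 0.048), so the first includes 0 and the question stays open. There 33 of 247 single-pass and secreted genes rose and 5 fell by limma, and 42 of 538 multi-pass genes rose and 24 fell. In the G3BP1 RIP 60 single-pass and secreted genes rose and 0 fell, and 138 multi-pass genes rose and 0 fell. In input 19 single-pass and secreted genes rose and 4 fell, while 11 multi-pass genes rose and 44 fell. Because the families were chosen from genes that rose in both RIPs, these counts are given without a test.

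Beyond input, 33 single-pass and secreted genes were higher and 1 lower in the G3BP1 RIP (median 0.003), and 135 multi-pass genes were higher and 1 lower (median 0.159). Of all 14232 genes 2421 were higher there. In the TIAR RIP the medians beyond input were -0.01 and 0.059. Without stress 91 single-pass and secreted genes were already higher in the G3BP1 RIP than in input and 4 lower.

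For each comparison of 3 arrays with 3, 1 of 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The real count and the highest other were 2609 and 0 (TIAR RIP stressed vs TIAR RIP unstressed), 3189 and 0 (G3BP1 RIP stressed vs G3BP1 RIP unstressed), 3026 and 2 (input stressed vs input unstressed), 9646 and 0 (TIAR RIP vs input, stressed), 9779 and 0 (G3BP1 RIP vs input, stressed), 8935 and 0 (TIAR RIP vs input, unstressed), 8765 and 1 (G3BP1 RIP vs input, unstressed), 9752 and 0 (TIAR RIP vs G3BP1 RIP, stressed) and 10310 and 0 (TIAR RIP vs G3BP1 RIP, unstressed). For the 497 shared TIAR and G3BP1 stress changes, such as EGR1 and VCAN, 1 of 100 drawn splits, the real one, gave as many, and the highest other gave 0. Since the other splits of the TIAR RIP arrays and of the G3BP1 RIP arrays called 0 and 0, that outcome was fixed, and it does not bear on whether the overlap exceeds chance.

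For the TIAR stress-granule set 2 of 20 assignments of the RIP arrays gave as many transcript clusters. They were the real one with 385 and the one with stressed and unstressed exchanged, with 1125; the rest gave 0. For the G3BP1 stress-granule set 1 of 20 did, with 1271 in the real one, 730 with the labels exchanged and 0 in the rest. The exchanged labels take the transcript clusters that fell with stress, and 20 assignments are too few for a share under 0.05.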
